A study of Mus musculus with 8 samples.

How the data were processed

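RNA was measured in the epidermis of mice treated with imiquimod, a Toll-like receptor 7 agonist that produces psoriasis-like skin inflammation when applied to mouse skin. Per the labels, the cells are keratinocytes, total RNA was extracted with TRIzol, libraries were made with the VAHTS Universal V6 RNA-seq kit, and all samples belong to 1 batch. The series holds 8 libraries in 2 genotypes, 4 from mice with an epidermis-specific knockout of Hnrnpu (cKO) and 4 from control mice (WT), and the design text gives 4 mice per genotype. Samples were grouped by the genotype in their labels and are named by genotype and replicate number. Only imiquimod-treated samples were analysed here, so no value without treatment is set beside these.

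The authors deposited a table of whole-number read counts per gene symbol and a table of FPKM values for the same genes and libraries. Per the submitters' processing notes, HISAT2 and HTSeq were used to make the counts. Their versions, the genome build, the annotation and the strand setting are not given in the sources used here, so no coordinates are printed, and reads from a gene and an antisense partner could not be told apart. How reads shared by near-identical gene copies were assigned is not given either, so values of the Sprr2, Stfa, Serpinb3, Krt6, Gsdma, Tmprss11 and haemoglobin families are uncertain for single members. The deposited FPKM values equal the count scaled by gene length and the column total: for 20863 of the 20863 genes with a count in at least 2 libraries, the implied length was the same in all libraries within a relative tolerance of 1e-04. The FPKM table therefore holds the same reads as the count table and was used only for alternative tests.

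The 23171 genes were tested on the deposited counts. Genes with too few counts were removed with filterByExpr, which left 14004, and library sizes were scaled with TMM factors. The edgeR quasi-likelihood test (edgeR 4.0.16, R 4.3.3) compared cKO with WT with no covariate, and p-values were adjusted over all tested genes by the Benjamini-Hochberg method. A gene is called at an adjusted p below 0.05. Standard errors of log2 fold changes are those implied by the F statistic. Levels are counts scaled to library size (CPM) with TMM factors, given as mean ± SD over 4 libraries. For single genes and list scores, a two-sided exact permutation test over all splits of 4 against 4 is added, for which the smallest possible p is 0.0286. All log2 fold changes are cKO over WT.

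Before the data were examined, 27 gene lists were fixed, 13 of pathways or gene families and 14 of cell type markers. The 25 with at least 5 tested members were tested with limma's camera on log2 CPM with a preset inter-gene correlation of 0.01 (limma 3.58.1), adjusted over the 25 lists. The camera test with a correlation estimated from these libraries and limma's fry test stand beside it. A list score is the mean over its members of log2 CPM centred on each gene's mean over the 8 libraries. Named genes were also chosen by a rule fixed before the data were examined. The rule takes a set of genes named whatever their result (Hnrnpu, Tnf, Il17a, Il17f, Il23a, Il1b, Il6, Krt16, S100a8, S100a9 and Mki67). It adds the 7 called genes with the largest rise and the 7 with the largest fall among those with a mean of at least 4 CPM and all cKO libraries on 1 side of all WT libraries, leaving out unnamed gene models and pseudogenes. It also takes up to 2 called members per list and direction by smallest p. Up to 2 members of each list that did not pass are given as values, those with the highest mean CPM. The value of 1 such member is not reported here. Genes named outside this rule are said to be so where they appear.

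Total counts per library ran from 37158621 to 38865722, and TMM factors from 0.934 to 1.08. On simulated counts with the means, spread and library sizes of these 8 libraries over 14004 genes, the test recovered 49% of 100 genes changed 2-fold and 89% of 100 genes changed 4-fold, with 144 genes called and 6 of these false. Genes were drawn independently and with the same spread in both genotypes, so these rates may not hold for the real libraries. Of 27 simulated lists the 1 shifted list was called and 0 of the others, but the simulated genes are independent, so this does not test correlation within lists. No within-genotype pair of libraries agreed within sampling noise, the lowest chi-square per degree of freedom over genes with at least 20 counts in the pair being 47.9, so all 8 were kept as separate replicates. Xist had at most 4 counts and Ddx3y at least 1888 in every library, so the 8 libraries do not differ in sex.

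Alternatives fixed beforehand were DESeq2 1.42.0, limma-voom, RLE factors, scaling by library size only, no low-count filter, a filter of at least 1 CPM in 4 libraries, limma on log2(FPKM + 1) and log2(FPKM + 0.1) for genes with a mean of at least 0.5 FPKM, limma on log2(FPKM + 1) without that filter, the replicate number as a block, and leaving out each library in turn. A pair of further alternatives for the gene lists, without near-identical families and with scaling by library size only, was chosen after seeing the data. GC content was taken from GENCODE M21 transcripts by gene symbol, and neighbouring genes from RefSeq on GRCm38.p6, used for gene order only.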

Results

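Expression was compared between Hnrnpu-knockout and control epidermis of imiquimod-treated mice, 4 libraries per genotype. Hnrnpu encodes a nuclear RNA-binding and matrix-associated protein of the heterogeneous nuclear ribonucleoprotein (hnRNP) family. The title of the series joins hnRNP-U to TNF-α in psoriasis, and the comparison asks which transcripts differ in inflamed epidermis when Hnrnpu is deleted there. Libraries held 37158621 to 38865722 counts, and 18265 to 18992 genes had at least 1 count. The first principal component of log2 CPM held 35.8% of the variance and had all cKO libraries on the negative side and all WT libraries on the positive side. The second component held 26.1% and spread the cKO libraries, at 36.7 and 56.8 for replicates 1 and 4 and at -35.8 and -27.7 for replicates 2 and 3, while WT libraries lay between -12.4 and 3.30.

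Hnrnpu was lower in every cKO library than in any WT library, but only in part. Its level was 307 ± 82.5 CPM in cKO and 437 ± 13.1 CPM in WT (SD, n = 4 each), a fitted 70.3% of WT (log2 fold change -0.51 ± 0.19 SE, 95% confidence interval -0.93 to -0.09). Single cKO libraries stood at 190, 373, 355 and 312 CPM for replicates 1 to 4, which is 43.4%, 85.3%, 81.1% and 71.3% of the WT mean. The difference did not pass the genome-wide threshold of the edgeR quasi-likelihood test (adjusted p = 0.191), and the exact permutation p was 0.0286, the smallest that 4 against 4 allows. Without cKO replicate 1 the log2 fold change was -0.33. The counts cover the whole gene, and the deleted part is not given in the sources used here, so transcripts that lack the deleted exons would still be counted.

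Tnf, the inflammatory cytokine named with hnRNP-U in the title, showed no difference that passed the test. It stood at 1.01 ± 0.558 CPM in cKO and 0.934 ± 0.531 CPM in WT (SD, n = 4 each), from 18 to 75 counts per library. The log2 fold change was 0.12 ± 0.51 (SE) with an edgeR adjusted p of 0.932, and its 95% confidence interval, -1.03 to 1.27, spans a fall to 0.488 times and a rise to 2.41 times the WT level. The sign turned when a single library was left out, to -0.30 without cKO replicate 4, -0.09 without WT replicate 1 and -0.04 without WT replicate 2. A difference in Tnf within this interval is not ruled out.

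**Figure D1:**
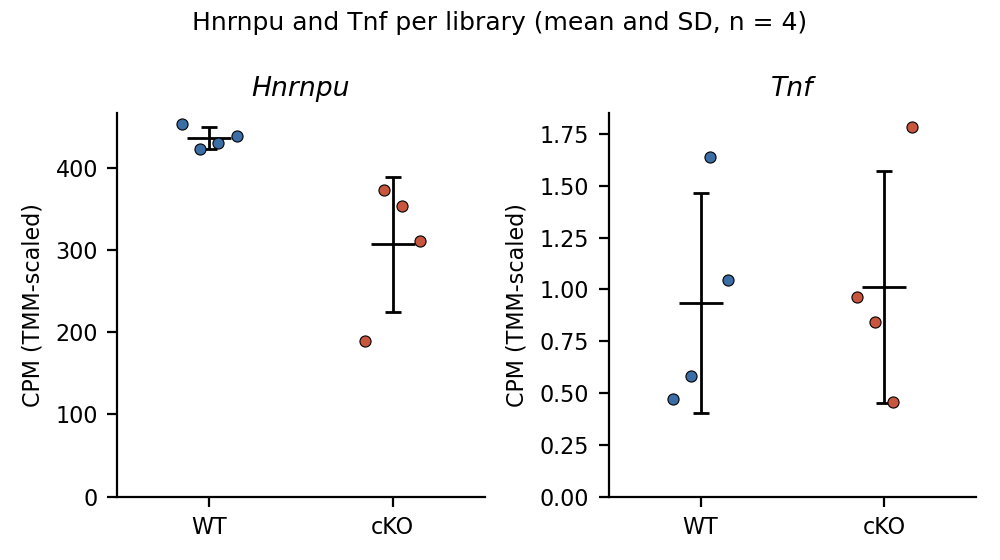
Hnrnpu (left) and Tnf (right) in CPM with TMM scaling on linear axes from 0, with a point per library, a horizontal mark at the mean and bars of 1 SD (n = 4 per genotype). The cKO libraries lie between 190 and 373 CPM for Hnrnpu, below the WT range of 424 to 455, and the genotypes overlap for Tnf.

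Across the transcriptome, 185 genes were called, 94 higher in cKO (80 of them at least 2-fold) and 91 lower (56 at least 2-fold). Among called genes with a mean of at least 4 CPM, the largest rises were of Gypc, a membrane skeleton-linked glycophorin, and Esr1, the estrogen receptor α. Gypc rose 41.9-fold, from 0.236 ± 0.0983 to 10.04 ± 3.26 CPM (log2 fold change 5.39 ± 0.38 SE, edgeR adjusted p = 0.00164). Esr1 rose 17.4-fold, from 0.698 ± 0.220 to 12.2 ± 3.74 CPM (4.12 ± 0.33, adjusted p = 0.00251). The small heat shock protein gene Cryab rose 10.7-fold (adjusted p = 0.0132). Sprr4, a small proline-rich protein of the cornified envelope, rose from 9.82 ± 7.42 to 70.6 ± 10.9 CPM (2.85 ± 0.52, adjusted p = 0.0362). Krt75, a keratin of the follicle companion layer, rose 6.56-fold (2.71 ± 0.26, adjusted p = 0.0061). Gsdma3, a gasdermin whose mutations cause hair loss in mice, rose 5.47-fold (adjusted p = 0.0115), and Ablim3, an actin-binding LIM protein, rose 7.17-fold (adjusted p = 0.0309).

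Among called genes of the same mean level, Tmprss11g, a transmembrane serine protease, fell most, 10.4-fold from 46.8 ± 30.6 to 4.52 ± 1.70 CPM (log2 fold change -3.38 ± 0.53 SE, edgeR adjusted p = 0.0301). Mmp9, gelatinase B, fell 7.64-fold from 17.1 ± 4.55 to 2.26 ± 2.04 CPM (-2.93 ± 0.57, adjusted p = 0.0439). Mmp9 ran from 0.571 to 5.21 CPM over the cKO libraries, and its log2 fold change was -3.74 without cKO replicate 2. Il33, an IL-1 family alarmin of keratinocytes, fell 5.36-fold from 246 ± 62.8 to 46.0 ± 23.5 CPM (-2.42 ± 0.37, adjusted p = 0.0294). The RNA-binding protein gene Igf2bp2 fell 8.80-fold (adjusted p = 0.0362) and the semaphorin gene Sema6d 5.60-fold (adjusted p = 0.0364). The matricellular protein gene Tinagl1 fell 5.04-fold (adjusted p = 0.0279) and the β-tubulin gene Tubb6 4.56-fold (adjusted p = 0.0348).

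In all 185 called genes the 4 cKO libraries lay on 1 side of the 4 WT libraries. The same held for 1552 tested genes (11.1%, where chance gives 2.86%), and 2602 genes had an unadjusted p below 0.05, where 700 are expected by chance. The count of called genes depended on single libraries. It was 20, 506, 66 and 213 without cKO replicates 1, 2, 3 and 4, and 34, 36, 8 and 23 without WT replicates 1, 2, 3 and 4, and DESeq2 called 1266. Of the 24 named genes that were called, 6, 24, 13 and 21 were still called without cKO replicates 1 to 4. Without WT replicates 1 to 4, 9, 10, 5 and 6 were still called. All 24 kept their direction in each of these fits. This is no separate check, since leaving out a library cannot turn a gene in which the genotypes do not overlap.

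**Figure D2:**
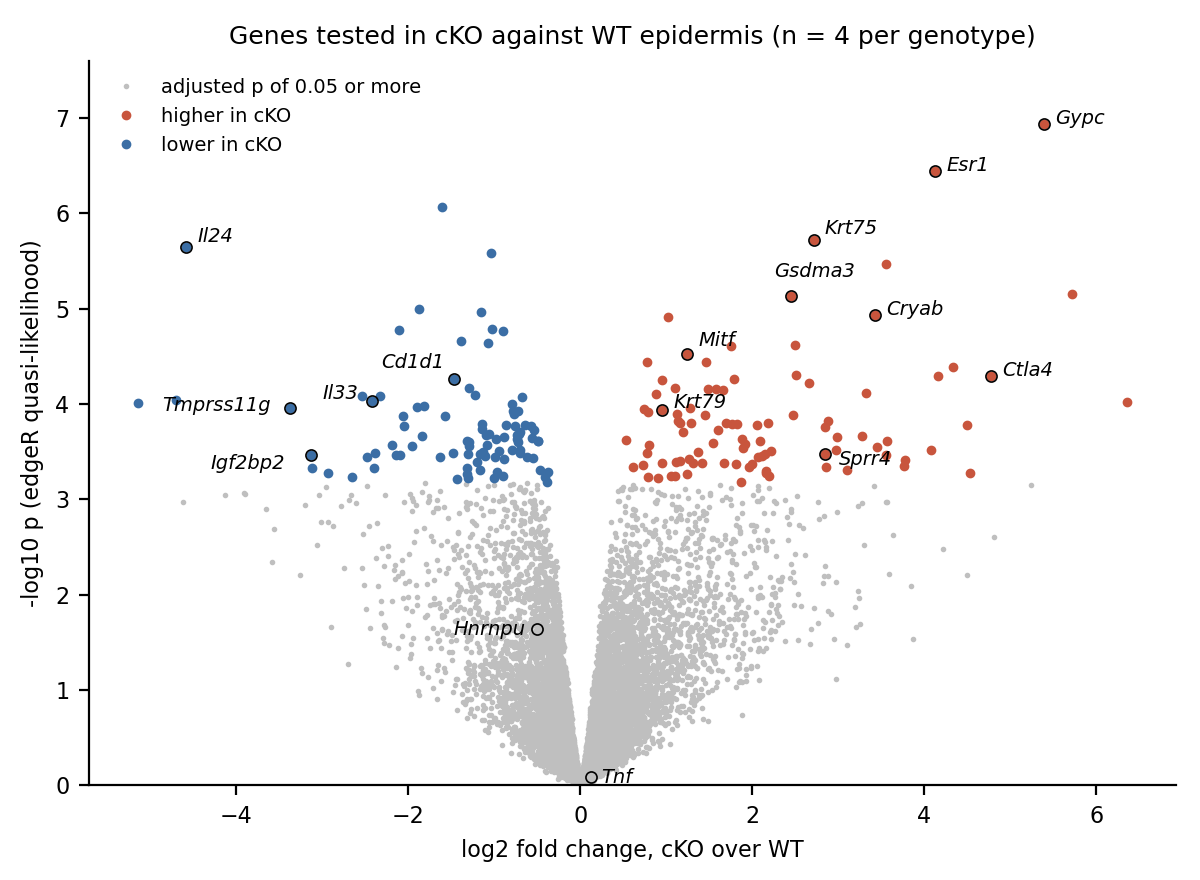
Log2 fold change of cKO over WT (x axis) against the -log10 p of the edgeR quasi-likelihood test (y axis) for the 14004 tested genes, a point per gene, with the 94 genes called higher in red, the 91 called lower in blue and a selection of named genes circled. Gypc and Esr1 have the smallest p-values, while Hnrnpu and Tnf lie among the genes not called.

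**Figure D3:**
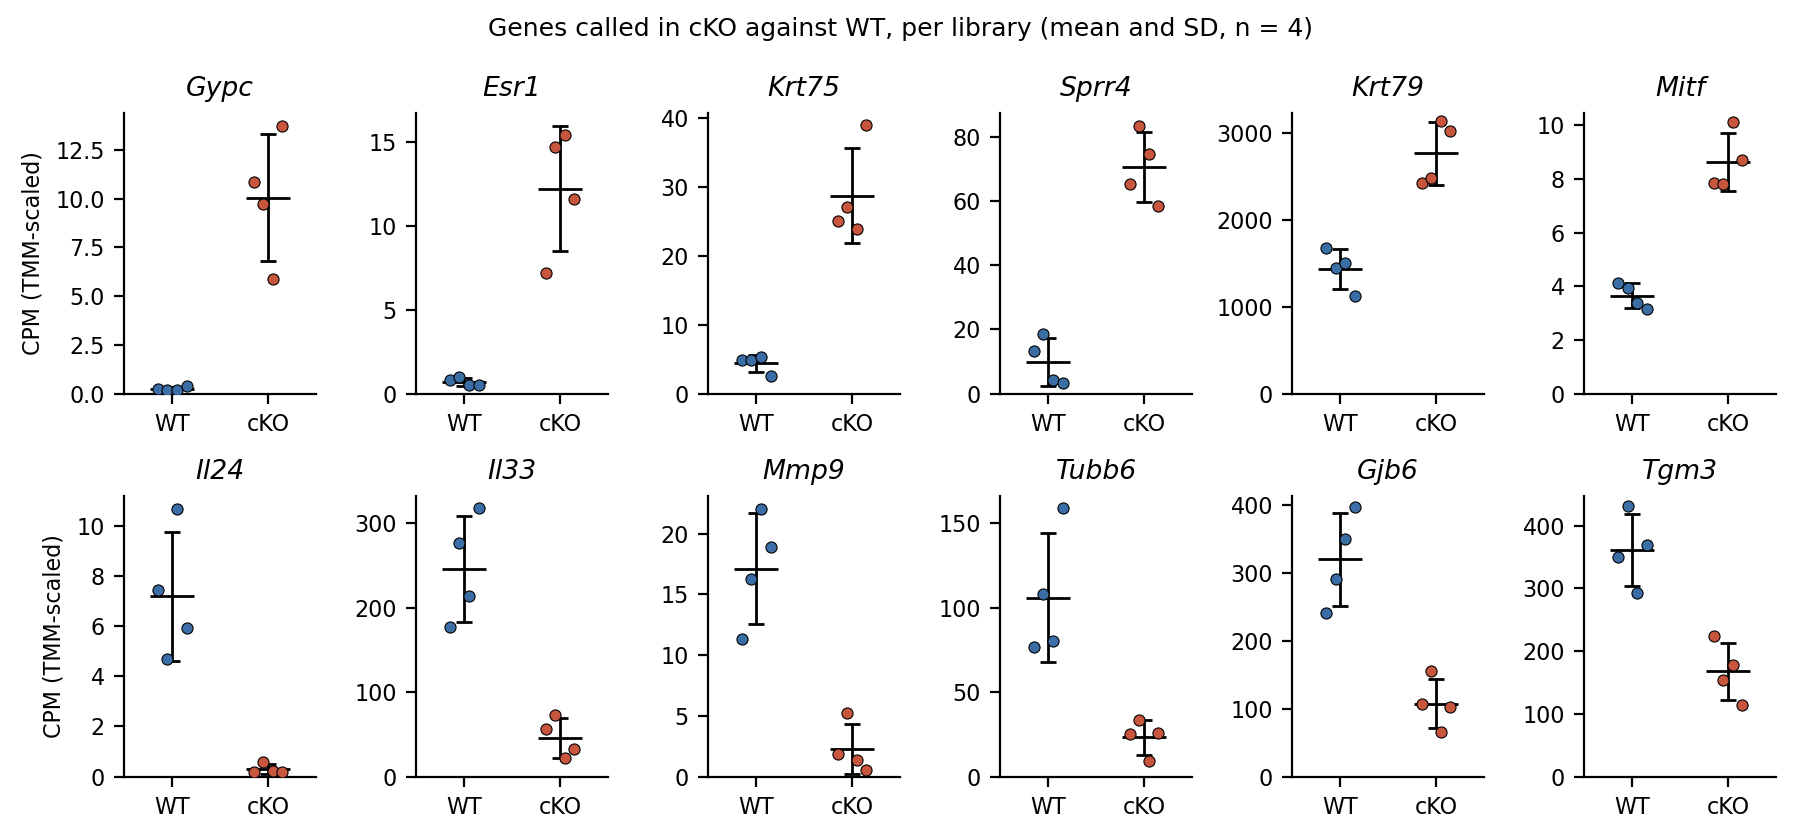
CPM with TMM scaling of 12 called genes on linear axes from 0, with a point per library, a horizontal mark at the mean and bars of 1 SD (n = 4 per genotype). The top row shows genes higher in cKO and the bottom row genes lower in cKO, and the genotypes do not overlap in any panel.

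All 15 outer root sheath and follicle stem cell genes had a positive fold change (median log2 fold change 0.80), and 3 of the 15 rose, 9 when adjusted over the list alone. Besides Krt75, these were Krt79, a keratin of the follicle infundibulum, which rose from 1432 ± 232 to 2763 ± 365 CPM (log2 fold change 0.95 ± 0.15 SE, edgeR adjusted p = 0.0301), and Lgr6, a stem cell receptor of the isthmus (1.11, adjusted p = 0.0386), which is named outside the rule after its value was seen. The 2 most abundant members that did not pass were Lrig1 (0.21 ± 0.19, adjusted p = 0.590) and Barx2 (0.34 ± 0.18, adjusted p = 0.339). The list passed camera (adjusted p = 3e-07), with an adjusted p = 0.459 with an estimated correlation.

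Of 17 sebaceous gland genes, 15 had a positive fold change (median 1.24). The lipid droplet protein gene Cidea was the 1 that rose (2.36-fold, adjusted p = 0.044 by edgeR), with 10 when adjusted over the list alone. Scd1, the stearoyl-CoA desaturase of sebocytes, stood at 1467 ± 745 CPM in cKO and 584 ± 192 CPM in WT without passing (log2 fold change 1.33 ± 0.39 SE, adjusted p = 0.118). Dgat2 was at 0.13 ± 0.25 (adjusted p = 0.826). The camera adjusted p was 1.37e-04, and the adjusted p = 0.468 with an estimated correlation. The list score of cKO replicate 4, -0.356, lay within the WT range of -0.862 to -0.167, below the other cKO libraries.

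All 10 melanocyte genes had a positive fold change (median 1.13), and 1 rose, or 4 when adjusted over the list alone. It was Mitf, the transcription factor that directs the melanocyte lineage, from 3.65 ± 0.460 to 8.63 ± 1.09 CPM (log2 fold change 1.24 ± 0.17 SE, edgeR adjusted p = 0.02). The pigment enzyme genes Dct (1.08 ± 0.29, adjusted p = 0.0905) and Tyrp1 (1.14 ± 0.26, adjusted p = 0.06) did not pass. Camera gave an adjusted p of 7.74e-06, and the adjusted p = 0.459 with an estimated correlation. Of 28 hair shaft and inner root sheath genes in the deposited counts, 11 passed the count filter, 5 with a positive and 6 with a negative fold change. Among the 11 none rose and 1 fell, against 1 higher and 4 lower when adjusted over the list alone. This was Tchh, trichohyalin of the inner root sheath (2.46-fold, -1.30 ± 0.23, adjusted p = 0.0337). Foxn1 (-0.78 ± 0.28, adjusted p = 0.181) and Hoxc13 (1.24 ± 0.34, adjusted p = 0.097) did not pass, and the list had a camera adjusted p of 0.115 (median -0.05).

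Of 28 stress keratin and activated-keratinocyte genes, 25 had a negative fold change (median log2 fold change -0.89) and 3 fell, 8 when adjusted over the list alone. Gjb6, the gap junction protein connexin 30, fell 2.97-fold from 320 ± 68.6 to 108 ± 36.4 CPM (-1.57 ± 0.25 SE, edgeR adjusted p = 0.0301). Plau, the urokinase plasminogen activator, fell 2.22-fold (-1.15 ± 0.19, adjusted p = 0.0319). The third was Gjb2, connexin 26, from 2017 to 564 CPM (-1.84, adjusted p = 0.0337), named outside the rule after its value was seen. The keratins of hyperproliferative epidermis did not pass. Krt16 stood at 3511 ± 1986 CPM in cKO and 7121 ± 1035 in WT (-1.02 ± 0.46, adjusted p = 0.276), and at -0.67 without cKO replicate 3. Krt6a stood at 4568 ± 3217 and 7717 ± 1927 (-0.76 ± 0.62, adjusted p = 0.556). The list passed camera (adjusted p = 3e-07), with an adjusted p = 0.459 with an estimated correlation. List scores were 0.0814, -0.646, -1.63 and 0.0583 in cKO replicates 1 to 4, all below the lowest WT score of 0.157.

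Basal keratinocyte and hemidesmosome genes passed camera as lower in cKO (15 of 20 negative, median -0.26, adjusted p = 0.0174), with an adjusted p = 0.459 with an estimated correlation. None of the 20 was called by edgeR, and 3 were lower when adjusted over the list alone. Krt14 was at -0.58 ± 0.24 (SE, adjusted p = 0.246) and Krt5 at -0.03 ± 0.19 (adjusted p = 0.953). Without cKO replicate 2 the list's adjusted p was 0.0733. Suprabasal and cornified-envelope genes passed camera as higher (27 of 36 positive, median 0.46, adjusted p = 0.0224), with an adjusted p = 0.749 with an estimated correlation. The only called member went the other way. Tgm3, the epidermal transglutaminase that crosslinks envelope proteins, fell 2.15-fold from 361 ± 57.4 to 168 ± 46.0 CPM (-1.11 ± 0.20, adjusted p = 0.0363). Adjusted over the list alone, 11 were higher and 1 lower. The abundant Krt10 (0.02 ± 0.22, adjusted p = 0.980) and Krt1 (-0.22 ± 0.18, adjusted p = 0.558) differed by less than the spread between libraries. This list did not pass without cKO replicate 2 (adjusted p = 0.61), cKO replicate 3 (0.0603), WT replicate 1 (0.0588) or WT replicate 4 (0.14). Of 30 barrier lipid enzyme genes none was called, with 3 higher and 1 lower adjusted over the list alone. Their median (-0.05) and mean (0.175) differ in sign, and the camera direction was down (adjusted p = 0.881), with Elovl4 at 0.45 ± 0.21 (adjusted p = 0.283) and Degs1 at -0.51 ± 0.13 (adjusted p = 0.0802).

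Among 25 cytokines and receptors of the psoriasis axis, 2 fell and none rose, with 3 lower and 2 higher when adjusted over the list alone. Il24, an IL-20 family cytokine made by keratinocytes, fell 24.0-fold from 7.20 ± 2.59 to 0.3 ± 0.194 CPM (log2 fold change -4.58 ± 0.45 SE, edgeR adjusted p = 0.0061). The other was Il33. The IL-17 cytokines had lower means in cKO without passing, Il17a at 0.891 ± 0.908 against 5.81 ± 7.52 CPM (-2.70 ± 1.22, adjusted p = 0.279). Il17a was above the cKO range only in WT replicates 3 and 4 (16.3 and 6.13 CPM), while WT replicates 1 and 2 (0.446 and 0.332 CPM) lay within the cKO range, and its log2 fold change was -1.37 without WT replicate 3 and -3.62 without cKO replicate 1. Il17f stood at 1.51 ± 1.59 against 6.67 ± 6.14 CPM (-2.14 ± 0.99, adjusted p = 0.285), and at -1.54 and -3.06 without these libraries. Il23a (-0.77 ± 0.73, adjusted p = 0.617) and Il1b (-1.28 ± 0.49, adjusted p = 0.206) did not pass. Il23a was at -0.44, -1.53 and -0.28 without cKO replicate 2, cKO replicate 4 and WT replicate 3, and Il1b at -0.63 without WT replicate 2. Il36rn (0.13 ± 0.32, adjusted p = 0.872) and Il36a (-0.16 ± 0.26, adjusted p = 0.794), the most abundant members, differed by less than the spread between libraries. Il6 had 0 to 3 counts per library and was not tested. The list did not pass camera (median -0.16, adjusted p = 0.0979), but it passed as lower on FPKM (0.0349), with library-size scaling (0.0314) and without WT replicate 1 (0.0367) or 2 (0.0438). It had an adjusted p = 0.746 with an estimated correlation.

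Of 26 TNF and NF-κB target genes, 1 fell, Mmp9, and none rose, with 2 lower when adjusted over the list alone. The most abundant members that did not pass, Nfkb1 (-0.19 ± 0.14 SE, edgeR adjusted p = 0.513) and Nfkbia (-0.22 ± 0.37, adjusted p = 0.802), are a subunit and an inhibitor of NF-κB. The list median was -0.14 and its camera adjusted p was 0.479. None of 21 antimicrobial and chemokine genes induced by IL-17 in keratinocytes was called, over all genes or adjusted over the list alone (median -0.37, camera adjusted p = 0.115). That list's call depended on single libraries. It passed as lower without cKO replicate 1 (adjusted p = 0.0265), cKO replicate 4 (0.0221) or WT replicate 1 (0.0383), on FPKM (0.0349) and with library-size scaling (0.0396). It had an adjusted p = 0.749 with an estimated correlation, and 0.973 without cKO replicate 3. The calprotectin genes varied widely between libraries of a genotype and did not pass, S100a8 at 2117 ± 1503 against 4320 ± 2833 CPM (-1.03 ± 0.62, adjusted p = 0.413). S100a9 stood at 2807 ± 2438 against 5501 ± 3922 CPM (-0.97 ± 0.75, adjusted p = 0.528). Without WT replicate 4 the log2 fold changes of S100a8 and S100a9 were -0.64 and -0.55, and that of S100a9 was -0.62 without cKO replicate 3 and -1.56 without cKO replicate 4.

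None of 38 cell cycle genes was called, over all genes or adjusted over the list alone (median 0.17, camera adjusted p = 0.273). Mki67 stood at 119 ± 40.5 CPM in cKO and 123 ± 20.7 in WT (-0.05 ± 0.25 SE, edgeR adjusted p = 0.949) and Hmgb2 at 0.31 ± 0.18 (adjusted p = 0.408). The p53 target list passed camera as higher (22 of 27 positive, median 0.30, adjusted p = 0.0174), with an adjusted p = 0.749 with an estimated correlation. No member was called, and 1 was higher and 1 lower when adjusted over the list alone. Its abundant members Cdkn1a (0.30 ± 0.24, adjusted p = 0.543) and Perp (-0.16 ± 0.14, adjusted p = 0.577) went opposite ways without passing. The list did not pass without cKO replicate 1 (adjusted p = 0.169) or cKO replicate 4 (0.0998). Its score was 0.734 and 0.472 in these 2 libraries. In cKO replicates 2 and 3 it was -0.274 and -0.148, within the WT range of -0.311 to -0.126. None of 17 type I interferon-stimulated genes was called by either count. Their median (-0.06) and mean (0.06) differ in sign, and the camera direction was down (adjusted p = 0.881), with Ifitm3 at 0.30 ± 0.28 (adjusted p = 0.605).

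Of 18 immediate early and stress-response genes none was called (median 0.10, camera adjusted p = 0.115, 3 higher adjusted over the list alone). Klf4 (0.03 ± 0.18 SE, edgeR adjusted p = 0.953) and Hspa1b (-0.11 ± 0.12, adjusted p = 0.655) differed by less than the spread between libraries. Of 25 other hnRNP genes none was called (median -0.06, camera adjusted p = 0.46, 1 higher and 2 lower adjusted over the list alone). Hnrnpk was at -0.11 ± 0.09 (adjusted p = 0.527) and Hnrnpa2b1 at -0.02 ± 0.10 (adjusted p = 0.933). Of 36 SR protein and core splicing factor genes none was called by either count (median -0.02, camera adjusted p = 0.236). Srsf3 stood at 288 CPM in both genotypes and Srsf1 at 0.11 ± 0.13 (adjusted p = 0.721).

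Neutrophil markers passed camera as lower in cKO (5 of 6 negative, median -0.97, adjusted p = 0.0368), with an adjusted p = 0.459 with an estimated correlation. Of 15 neutrophil markers in the deposited counts only these 6 passed the count filter, and Hdc among them is also a mast cell marker. Macrophage and monocyte markers also passed as lower (15 of 16 negative, median -0.30, adjusted p = 0.0368), with an adjusted p = 0.746 with an estimated correlation. Erythroid genes, a sign of blood, were lower as a list (5 of 5 negative, median -0.81, camera adjusted p = 0.0174), with an adjusted p = 0.459 with an estimated correlation. No member of these lists was called, and adjusted over the list alone 2 erythroid genes were lower and none of the others. The most abundant members were the neutrophil genes Cxcr2 (-0.85 ± 0.48 SE, edgeR adjusted p = 0.379) and Il1r2 (0.18 ± 0.68, adjusted p = 0.922) and the macrophage genes Csf1r (0.25 ± 0.35, adjusted p = 0.757) and Ccr2 (-0.89 ± 0.57, adjusted p = 0.437). For blood they were the haemoglobin genes Hbb-bs (-1.19 ± 0.39, adjusted p = 0.153) and Hba-a1 (-0.69 ± 0.43, adjusted p = 0.427). The neutrophil list did not pass without WT replicate 2 (adjusted p = 0.0728), and the macrophage list without cKO replicates 2, 3 and 4 (adjusted p = 0.23, 0.0885 and 0.144) or WT replicates 1 and 4 (0.0588 and 0.087). The macrophage score of cKO replicate 1, 0.676, was above every WT score (-0.101 to 0.497), and without that library the list's adjusted p was 1.25e-05.

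In the T cell list, Ctla4, an inhibitory receptor of activated and regulatory T cells, rose from 0.0336 ± 0.0258 to 1.01 ± 0.574 CPM (log2 fold change 4.77 ± 0.68 SE, edgeR adjusted p = 0.0262), while 9 of 13 members were negative. The list median (-0.33) and mean (0.48) differ in sign, its camera direction was up (adjusted p = 0.115), and 3 members were higher when adjusted over the list alone. Cd3g (-0.63 ± 0.59, adjusted p = 0.613) and Cd247 (-0.78 ± 0.67, adjusted p = 0.571) of the T cell receptor complex did not pass. In the Langerhans and dendritic cell list, 12 of 14 members were positive (median 0.40, camera adjusted p = 0.115). The called member, Cd1d1, which presents lipids to natural killer T cells, fell 2.78-fold (-1.47 ± 0.21, adjusted p = 0.0262), with 1 higher and 1 lower adjusted over the list alone. Cd74 (0.49 ± 0.32, adjusted p = 0.443) and H2-Ab1 (0.37 ± 0.33, adjusted p = 0.59) did not pass.

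No fibroblast, endothelial or adipocyte marker was called. The 14 fibroblast genes had a median of 0.26 (camera adjusted p = 0.115, 1 higher adjusted over the list alone). Postn, the gene of a matrix protein of the dermis, stood at 258 ± 62.3 against 120 ± 39.6 CPM (log2 fold change 1.11 ± 0.24 SE, edgeR adjusted p = 0.0553) and Sparc at -0.34 ± 0.37 (adjusted p = 0.674). All 5 tested endothelial genes, of 14 in the deposited counts, were negative (median -0.46, camera adjusted p = 0.113, none adjusted over the list alone). Among them were Flt1 (-0.46 ± 0.89, adjusted p = 0.83) and Egfl7 (-0.46 ± 0.41, adjusted p = 0.59). Of 7 adipocyte genes, 3 were higher and 1 lower adjusted over the list alone (median 0.43, camera adjusted p = 0.0979), with Lpl at 0.97 ± 0.28 (adjusted p = 0.11) and Fabp4 at -2.36 ± 0.70 (adjusted p = 0.123). The mast cell and skeletal muscle lists had 2 tested members each and were not tested as lists, with 1 mast cell gene higher and 1 lower adjusted over the list alone. Kit was at 1.14 ± 0.42 (adjusted p = 0.196), Hdc at -2.12 ± 0.87 (adjusted p = 0.232). Of the muscle genes, Mylpf was at -0.40 ± 0.31 (adjusted p = 0.523) and Tnni2 at -0.40 ± 0.27 (adjusted p = 0.463).

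Of the 25 tested lists, 10 passed camera with the preset correlation, 5 higher and 5 lower in cKO, and none passed with an estimated correlation. The fry test called 0 of the 25 lists at an adjusted directional p below 0.05. Its mixed test, which asks for changes in either direction, called 11 of the 25. These were the psoriasis cytokine (adjusted p = 5.32e-05), T cell (3.66e-04), outer root sheath (6.39e-04), hair shaft (9.13e-04), melanocyte (9.13e-04) and basal (0.00361) lists, and the adipocyte (0.007), TNF target (0.0118), stress keratin (0.0122), hnRNP (0.0197) and sebaceous (0.0209) lists. The mixed test does not compare a list with other genes, and 2602 of the 14004 tested genes had an unadjusted edgeR p below 0.05. A call by it therefore does not set a list apart from other genes. List scores of the genotypes did not overlap in 4 lists (outer root sheath, melanocyte, stress keratin and basal), each with an exact permutation p of 0.0286, the smallest possible, and a Benjamini-Hochberg adjusted p of 0.179 over the 25 lists.

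**Figure D4:**
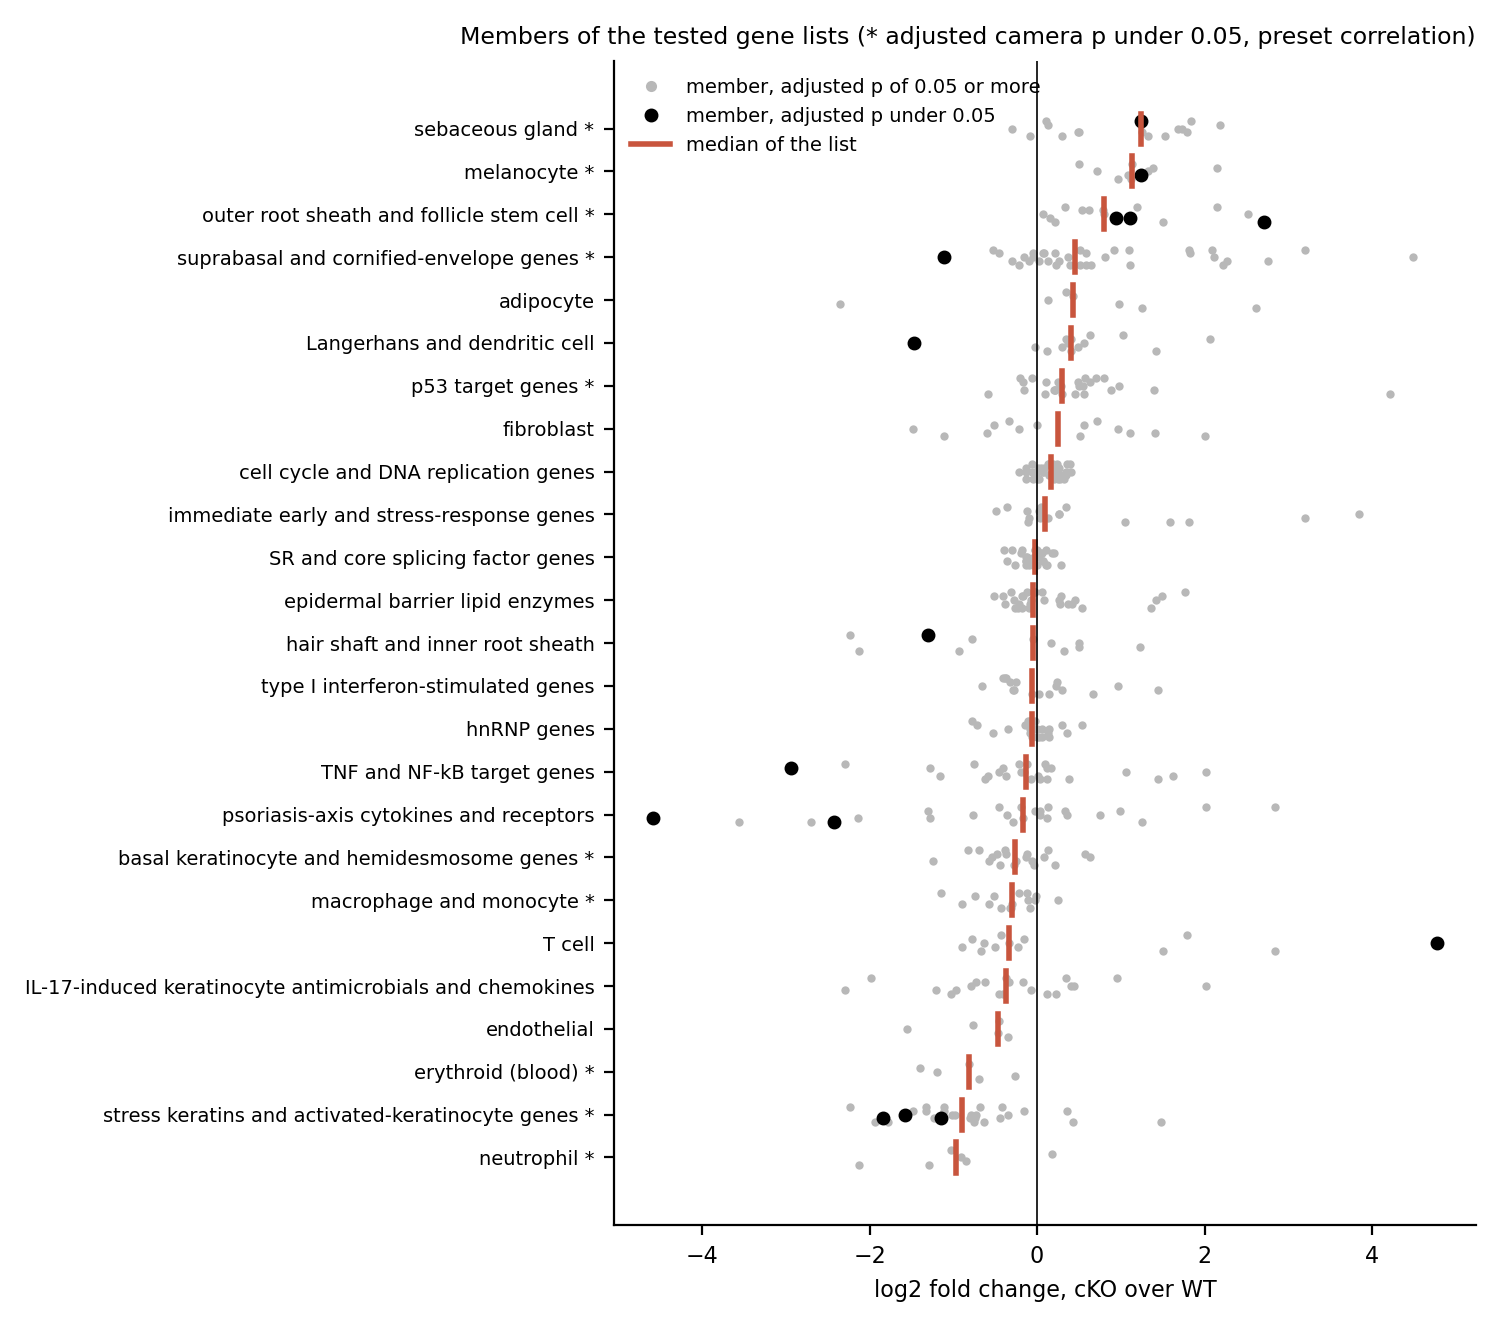
Log2 fold change of cKO over WT (x axis) of each tested member of the 25 tested gene lists (rows, ordered by median), with called members in black, others in grey and the list median as a red bar. Asterisks mark the 10 lists that passed camera with the preset correlation. The medians run from -0.97 for neutrophil markers to 1.24 for sebaceous gland genes.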

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

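The GC content tests and the counts over other splits of the libraries were planned before their results were seen, and the tests of the keratinocyte share, of near-identical families, of a mislabelled library and of immune and stromal cells were chosen afterwards. Of 118 groups of 4 libraries examined, 7 held a library far from the other 3, where chance gives about 1 in 20, or 5.9. In WT, Krt75 stood at 2.49 CPM in replicate 4 against 4.84 to 5.28 in the others, Gsdma3 at 0.944 CPM in replicate 3 against 1.73 to 1.85, and Plau at 131 CPM in replicate 4 against 108 to 111. In cKO, Tmprss11g stood at 1.97 CPM in replicate 4 against 5.24 to 5.57, Tinagl1 at 20.2 CPM in replicate 2 against 7.83 to 8.97, and Il24 at 0.588 CPM in replicate 2 against 0.182 to 0.241. The endothelial list score was 0.912 in WT replicate 3 against 0.0919 to 0.193. None of these libraries crossed into the range of the other genotype for the 6 genes. This is no separate check, since the genotypes do not overlap in any of the 185 called genes.

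Chance assignment of the libraries is argued against for the number of called genes. Among the 35 splits of the 8 libraries into 4 and 4, the real one gave 185 called genes and the highest of the others 0, so 1 split gave as many. Chance cannot be excluded for the number of gene lists that passed camera with the preset correlation, since the real split gave 10 lists, the highest of the others 16, and 14 of the 35 splits gave as many.

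The outer root sheath, sebaceous gland and melanocyte lists passed camera as higher in cKO, with 5 of 42 members called, but not with an estimated correlation (adjusted p = 0.459, 0.468 and 0.459). A lower share of the main keratinocytes would raise markers of every other cell type alike. The scores of the macrophage, endothelial, fibroblast and hair shaft lists shifted by -0.292 on average, the fibroblast score alone upward. The 3 lists shifted by 0.975, a difference of 1.27 (exact permutation p = 0.0286, the smallest possible). Those 4 lists were picked with their directions known, and the 3 lists because they rose, which favours a difference above 0. Against all 9 other tested marker lists, 4 of them shifted upward and their mean shift -0.208, the difference was 1.18 (exact permutation p = 0.0286). The other lists did not rise alike, but a weaker imiquimod reaction may lower the immune lists, so a lower keratinocyte share is not excluded. A bias from GC content or gene length is argued against by the small trend on either across genes (Spearman rho -0.044 and -0.037). Its removal left the median log2 fold change of the 42 members at 1.12 (95% bootstrap interval 0.734 to 1.25). This interval resamples genes, so it leaves out the spread between mice. A hypothesis that stays open is that pilosebaceous cells and melanocytes, or their transcripts, may be more abundant in this epidermis when Hnrnpu is deleted, and more follicle taken along with the cKO epidermis, which was not tested, may give the same pattern.

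The stress keratinocyte list passed camera as lower in cKO, with 3 of 28 members called, but not with an estimated correlation (adjusted p = 0.459) or by fry (adjusted p = 0.146). After the same small trend on GC content and length was removed, the median of the 28 members was -0.93 (95% bootstrap interval -1.22 to -0.744), which argues against that bias. Reads shared between near-identical copies are argued against as the whole source by the 12 members outside the Sprr2, Stfa, Serpinb3 and Krt6 families, whose median was -1.09 (-1.52 to -0.703). Both intervals resample genes and leave out the spread between mice. A weaker imiquimod reaction in the cKO mice may also lower these genes, whether it comes from the genotype or from the dose each mouse received, and these cannot be separated with treated mice alone.

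Hnrnpu was lowered only in part. A WT library under a cKO label is argued against because the highest cKO library lay 50.9 CPM below the lowest WT library. The gap does not show how complete the deletion was in each mouse, and cKO replicate 2 stood at 85.3% of the WT mean. For a higher share of immune and stromal cells that keep the gene, the mean shift of 6 immune and stromal lists was -0.142 (exact permutation p = 0.371). The T cell, Langerhans and fibroblast scores rose, and the neutrophil, macrophage and endothelial scores fell. The largest rise was of the T cell list, from a mean score of -0.283 in WT to 0.283 in cKO. However, 9 of its 13 tested members had a negative fold change (median -0.33), so the score does not show a rise of T cells. Scores that moved in opposite ways cancel in this mean, which does not measure the share of these cells together. The melanocyte list, which was higher in cKO, was not among the 6. A higher share of cells that keep the gene is thus not excluded with 4 libraries per genotype. Keratinocytes that escaped deletion and transcripts that lack only the deleted part may both leave counts, and neither was tested, since the counts are per gene.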

How the results depend on the processing

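The list alternatives without near-identical families and with library-size scaling only were chosen after seeing the data. Against 185 called genes (94 higher, 91 lower), DESeq2 gave 1266 (691 and 575), no low-count filter 349 (177 and 172), and limma on log2(FPKM + 1) without a filter 19 (11 and 8), with 185, 177 and 17 shared. Leaving out a library gave 8 to 506 genes (5 to 251 higher, 3 to 255 lower), with fewer samples per fit, and the causes of the other moves were not tested. The other tests, scalings and filters gave 146 to 256. The median log2 fold change of all genes was -0.001 to 0.074 under the 18 alternatives. All 24 called named genes kept their direction wherever tested, and Gypc, Esr1, Krt75 and Il24 were called under all 18 alternatives. The genotypes do not overlap in these 24 genes, so the kept direction adds little to the call. Hnrnpu stayed negative and not called under all 18 (adjusted p 0.113 to 0.362), from -0.60 to -0.33 with a library left out.

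Tnf was not called under 17 alternatives (adjusted p 0.691 to 0.985; too few counts for the filter of 1 CPM) and ran from -0.30 to 0.53 with a library left out. Mki67 was 0.01432 with library-size scaling and ran from -0.22 to 0.17 with a library left out.

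Of the 25 tested lists, 10 passed camera. With an estimated correlation 0 of the 25 passed and by fry's directional p 0, with a library left out 7 to 13 (7 to 10 of them shared with the 10), without near-identical families 10 (10 shared) and with library-size scaling 13 (10 shared). The direction turned, without a call, for barrier lipid enzymes (adjusted p 0.92, 0.0998 and 0.581 without cKO replicates 1 and 4 and WT replicate 3, lowest 0.0656 without cKO replicate 2), interferon genes (0.987 by fry, 0.828 with the stricter filter, 0.947 on FPKM, 0.872 and 0.712 without cKO replicate 4 and WT replicate 3, lowest 0.364 without WT replicate 4), T cells (0.873 with the stricter filter, 0.752 on FPKM), TNF targets (0.623 without WT replicate 3, and 0.12 to 0.848 with each library left out in turn), cell cycle (0.295 without cKO replicate 4) and hnRNP genes (0.973 without cKO replicate 3). The cause was not tested. Beside the cytokine and IL-17 lists, 9 lists passed under an alternative only. Passing as higher were cell cycle (4.6e-06 without cKO replicate 3), immediate early (0.00496 without WT replicate 3), Langerhans (8.26e-05 without cKO replicate 4), T cell (0.0332, 0.0468 and 0.019 without cKO replicate 4, WT replicate 3 and WT replicate 4), fibroblast (0.0121 without WT replicate 2) and adipocyte genes (0.0221 without cKO replicate 4). Passing as lower were SR (0.0395 without cKO replicate 4), endothelial (0.0374 without cKO replicate 1) and hair shaft genes (0.0396 with library-size scaling).

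With the replicate number as a block, 216 genes were called (124 higher, 92 lower), 98 of them shared, and 10 lists, Hnrnpu was at -0.55 (adjusted p = 0.192), Tnf at 0.16 (0.91), and barrier lipid enzymes turned direction (0.958). The numbers are not shown to pair the samples: same-numbered libraries correlated at -0.1, 0.13, 0.1 and 0.19 in their deviations from the genotype means, and not every library correlated best with its own number.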

Other observations

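The genes named in this part, apart from Hnrnpu, and its tests other than the genome-wide edgeR test were chosen after the results were seen. Among called genes outside the fixed lists, Socs3, a feedback inhibitor of cytokine signalling, fell from 78.7 to 25.3 CPM (log2 fold change -1.64, edgeR adjusted p = 0.0363), Clcf1, a ligand of the IL-6 family, from 28.1 to 6.75 CPM (-2.06, adjusted p = 0.0308), and Il4ra, the IL-4 receptor α chain, from 146 to 68.0 CPM (-1.10, adjusted p = 0.0336). Has3, a hyaluronan synthase, fell from 67.6 to 17.4 CPM (-1.96, adjusted p = 0.035), and Itga5, the α5 integrin, from 13.8 to 5.24 CPM (-1.39, adjusted p = 0.0172). Cst6, an inhibitor of cathepsins in the epidermis, rose from 565 to 1943 CPM (1.78, adjusted p = 0.0262), Gata6, a transcription factor of the sebaceous duct, from 3.37 to 11.9 CPM (1.82, adjusted p = 0.0308), and the cell cycle regulator Ccnd2 from 38.9 to 116 CPM (1.58, adjusted p = 0.0276).

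Fkbp5 (log2 fold change 1.27, edgeR adjusted p = 0.0301), Tsc22d3 (1.05, adjusted p = 0.0456) and Zbtb16 (2.08, adjusted p = 0.0337), which glucocorticoids induce, all rose. As a hypothesis, a wider glucocorticoid response may stand behind them, but 15 other tested glucocorticoid-responsive genes had a median of 0.04, with 8 of them positive, none called, and a camera p of 0.178. The fry mixed p of these 15 genes was 0.0542. A different time of day at sampling, which also moves such genes, had no measured sign in 8 clock-controlled genes (fry mixed p = 0.678, exact permutation p of the list score 0.857). Npas2, a clock transcription factor outside that list, rose from 0.116 to 0.527 CPM (2.16, edgeR adjusted p = 0.0429). Neither explanation is excluded.

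Of the 94 genes higher in cKO, 27 (28.7%) had a WT mean below 0.5 CPM, while 9 of the 91 lower genes (9.89%) had a cKO mean below 0.5 CPM (odds ratio 3.65, 95% confidence interval 1.54 to 9.44, Fisher exact p = 0.00144). Examples are Ttr (0.0342 and 3.03 CPM in WT and cKO), Cldn3 (0.0408 and 2.30 CPM) and Wfdc3 (0.315 and 5.68 CPM), with Gfpt2 the other way (1.92 and 0.0526 CPM). The genes that rose also had larger changes (median absolute log2 fold change 1.87 against 1.15) and lower levels in the genotype where they were higher (median 10.3 against 38.6 CPM). Both put more of them below 0.5 CPM, and 1087 tested genes lay below it in WT against 933 in cKO. Whether silent genes are switched on in cKO more often than active genes are switched off cannot be told apart from these differences here.

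Genes next to Hnrnpu, which may carry strain differences around a targeted locus, did not stand out: 11 of the 50 nearest tested genes (22%) on GRCm38.p6 had an unadjusted p below 0.05 against 18.6% of the others (Fisher exact p = 0.584, odds ratio 1.24, 95% confidence interval 0.571 to 2.47), and 0 of the 50 were called by edgeR. The interval leaves a moderate excess open.

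If the expression change scaled with the loss of Hnrnpu, cKO replicate 1, with the least Hnrnpu, may be expected to shift most. Along the 200 genes with the smallest p in the fit without the library in question, its shift was 0.834 of that of the other cKO libraries, against 0.554, 0.882 and 0.781 for replicates 2, 3 and 4. The difference from their mean, 0.095, is smaller than their SD of 0.168, so 4 libraries do not decide it. The genes were chosen with the other cKO libraries in the fit, which favours the shift of those libraries. A ratio below 1 therefore does not by itself mark a smaller shift. The cKO libraries also differed in inflammation genes: the score of the list induced by IL-17 was 0.56, -0.666, -1.56 and 0.652 in cKO replicates 1 to 4 and -0.255, 0.0925, 0.878 and 0.301 in WT replicates 1 to 4.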
